A study of Homo sapiens with 4 samples.

How the data were processed

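Total RNA was profiled on an Affymetrix whole-transcript array in 4 samples of A549 cells carrying a short hairpin RNA against LDOC1, 2 with the H2B mutant H2BK120R and 2 with the empty vector. Per the labels' protocols, RNA was extracted with a column kit from cultures above 90% confluency, and amplified RNA was turned into single-stranded cDNA, fragmented and labelled with biotin. The groups and replicate numbers were taken from the sample titles.

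The deposited table holds 1 value per probe set and array. The values are log2 levels that the authors had normalized between arrays before they deposited them. The base of 2 is inferred from their range, 1.56 to 19.15, and the normalization from the near-equal medians of the 4 arrays. The submitters' processing notes name MAS5 and give no version. That method was made for older 3' arrays, and how it was applied here, the background correction, the probe summary and any detection calls are not given in the sources used here. A wrong base would rescale every difference in the text and leave the p-values as they are. Genes were named through GEO's platform annotation, and the symbols were checked by gene ID in the RefSeq table for GRCh38.p14, where 0 needed an update. Of 21448 probe sets, 17709 had 1 gene symbol, 0 had several and 3739 were unnamed here. All 17709 gene IDs matched that table. For the 22 probe sets that shared their gene with a brighter one, the brighter stood for the gene, which left 17687 genes. No genome build is named for the values, so no coordinates are given. For arrays, the number of arrays limits the precision.

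No 2 arrays were copies: between 207 and 309 of the 21448 values were identical in a pair, at the 2 decimals of the table. The standard deviation of the difference between 2 arrays was 0.38 for the pair with H2BK120R, 0.46 for the vector pair and between 0.39 and 0.49 for pairs across the groups.

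H2BK120R was compared with vector by limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend) on the values as deposited, two-sided, without a covariate, and with Benjamini-Hochberg adjustment over all probe sets. The fit had 2 residual degrees of freedom and borrowed 8.95 prior degrees of freedom across probe sets. Gene lists were compared with all other probe sets by camera in limma, with a preset inter-gene correlation of 0.01, at least 5 measured members and adjustment over 44 lists. The lists held 1303 symbols, of which 1167 were measured and 136 were unmatched. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

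The samples, the tests, the alternatives, the gene lists and the rule for named genes were chosen before the data were examined. The rule took, in each direction, the 12 genes with the largest log2 difference among probe sets with 1 gene symbol, an adjusted p under 0.05, both arrays of one group above both of the other, and a mean in the brighter group at or above the median level of 6.41. Where fewer passed, the list was filled with the smallest unadjusted p-values that met the other conditions. Since 0 passed, all 24 were filled in this way. LDOC1, every measured H2B gene and up to 4 members of each described list with the smallest p were also named. The lists that passed were also compared with 10000 random lists matched on mean level or on genomic length in 20 bins, and 17 gene families, picked by symbol after the results were seen, were tested with camera in the same way.

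The test was tried on simulated data with 21448 genes and the spread of these arrays, in 5 runs per size. It recovered 17.3%, 89.9% and 99.6% of 200 genes changed by 1, 2 and 3 on the log2 scale, and made 0.2 calls on average with no gene changed. With no list shifted, camera called 0.05 of 44 lists on average over 20 runs. Genes were simulated independently of each other. In the real arrays the estimated correlation was 0.30 for replication histones other than H2B and 0.16 for mitosis. The simulated rate therefore does not cover lists whose genes vary together. A shift of the ribosomal list by 0.2 was called in 100% of runs with the preset correlation and in 0% with an estimated one.

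The alternatives were quantile normalization, equal array medians, leaving out the dimmest 25% or 50% of probe sets, testing only probe sets with 1 gene symbol, eBayes without the trend or with robust estimation, the replicate number as a block, and leaving out each array in turn. For the gene lists they were an estimated correlation, camera on ranks and fry, and for the fold threshold 1.5-fold in place of 2-fold. A change of pseudocount was planned for linear values and does not apply to log2 values. Quantile normalization moved the median difference over all probe sets to -0.0013 and equal medians to -0.02. The count at an unadjusted p under 0.05 was added after seeing that no probe set passed.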

Results

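The series profiled RNA from A549 cells, an established human lung adenocarcinoma line, in which the gene LDOC1 had been depleted by a short hairpin RNA. LDOC1 encodes a small leucine zipper protein of the retrotransposon-derived RTL family. Of the 4 arrays, 2 came from depleted cells that also expressed H2BK120R, a histone H2B whose lysine acceptor for monoubiquitin is replaced by arginine, and 2 came from depleted cells carrying the empty vector. According to the submitters' design text, LDOC1 depletion raised monoubiquitylated H2B (H2Bub1) and the mutant histone lowered it again. The comparison thus asks which transcripts differ once that mark is reduced in LDOC1-depleted cells. The arrays did not measure H2Bub1. No array came from cells with an unmutated H2B construct, so the mutation cannot be told apart from the expression of added histone. Cells with intact LDOC1 were not analysed here. Each array gave a log2 level for 21448 probe sets, with medians between 6.40 and 6.43. Pearson correlations across probe sets ranged from 0.990 to 0.994 over the 6 pairs of arrays. Vector replicate 1 had the lowest mean correlation with the others, 0.991. The labels do not say that the replicates came from separate cultures. The limma p-values of single genes thus measure the spread between these arrays, which may be technical. The camera p-values with the preset correlation compare a list's genes with other genes and take members as nearly independent. They do not measure the spread between arrays or cultures.

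LDOC1 itself (probe set TC0X00010989.hg.1) was measured at 8.52 ± 0.21 (SD, n = 2) in the cells with H2BK120R and at 8.17 ± 0.23 (SD, n = 2) in the vector cells. The difference of 0.35 on the log2 scale had a standard error of 0.23 and a limma adjusted p of 0.790, and was 0.19 without vector replicate 1 and 0.21 without H2BK120R replicate 2. Both groups carry the hairpin, so this value compares 2 depleted lines and does not measure the depletion. The H2B genes, which encode the histone that carries the mark, were not called as shifted, which does not show that they were equal. Of 20 H2B genes listed, 17 had a probe set, and 11 of these were lower with H2BK120R, 5 were higher and 1 was equal. Their median difference was -0.09 (camera adjusted p = 0.533, and 0.780 with an estimated correlation). The median was 0.03 without H2BK120R replicate 2 and -0.14 without H2BK120R replicate 1. The brightest were H2BC12, H2BC14 and H2BC18. H2BC12 was at 17.87 ± 0.08 with the mutant and 17.97 ± 0.13 with the vector (SD, n = 2 each), and H2BC18 was at 17.35 in both groups. H2BC10 had the smallest unadjusted p among the H2B genes, with a difference of -0.26 ± 0.15 (SE) and a limma adjusted p of 0.777. H2B genes are near-identical copies, so a probe set may also read other members or the introduced construct, and which copy the construct was made from is not given in the sources used here.

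**Figure D1:**
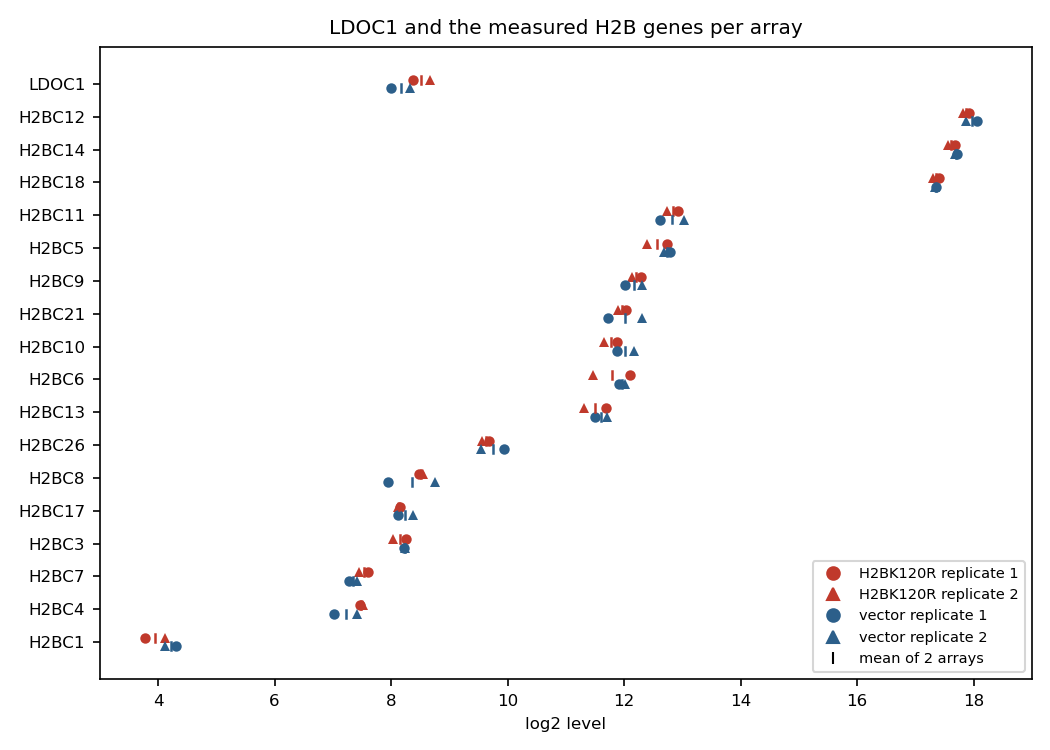
Log2 levels (horizontal axis) of LDOC1 and the 17 measured H2B genes (rows), with red for H2BK120R and blue for vector, circles for replicate 1, triangles for replicate 2 and a vertical tick for the mean of each group's 2 arrays. LDOC1 has a mean of 8.52 with H2BK120R and 8.17 with the vector, and H2BC18 has a mean of 17.35 in both groups.

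At the level of single genes, the transcripts with the smallest p-values among those lower with H2BK120R included small subunits of the respiratory chain, the ribosome and the spliceosome, and none passed the adjusted threshold. COXFA4, formerly NDUFA4 and a subunit of cytochrome c oxidase, was at 11.82 ± 0.08 with the mutant and 12.73 ± 0.16 with the vector (SD, n = 2 each). Its difference was -0.91 ± 0.14 (SE), with the smallest unadjusted p of all genes named and a limma adjusted p of 0.492. NDUFA1, a subunit of respiratory complex I, differed by -0.88 ± 0.14 and COX6C, another cytochrome c oxidase subunit, by -0.75 ± 0.17. PET100, an assembly factor of the same oxidase, differed by -1.07 ± 0.26. The ribosomal protein genes RPL30, RPS29 and RPL41 differed by -0.66 ± 0.16, -0.57 ± 0.13 and -0.45 ± 0.11. SNRPD2 and SNRPE, which encode Sm proteins of the spliceosome core, differed by -0.66 ± 0.13 and -0.61 ± 0.14. The remaining 3 of the 12 genes on this side were POLE4, an accessory subunit of DNA polymerase epsilon (-0.92 ± 0.17), CRIP1, a LIM-domain protein (-0.79 ± 0.19), and TIPARP, a mono-ADP-ribosyltransferase induced by the aryl hydrocarbon receptor (-0.60 ± 0.15). The errors are limma's standard errors.

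Among the 12 genes named on the higher side, the largest differences were those of GPR135, an orphan G protein-coupled receptor, and TAS2R31, a bitter taste receptor. GPR135 was at 7.81 ± 0.03 with H2BK120R and 6.52 ± 0.03 with the vector, and TAS2R31 at 8.29 ± 0.11 and 7.03 ± 0.10 (SD, n = 2 each). Their differences were 1.29 ± 0.24 and 1.26 ± 0.23 (SE), each with a limma adjusted p of 0.492. SNRPA, a U1 snRNP protein of the spliceosome, differed by 0.73 ± 0.15, opposite in sign to the Sm genes. CEP128, a centriole protein, differed by 0.70 ± 0.16 and IFNAR2, a chain of the type I interferon receptor, by 0.59 ± 0.14. TFPI, the tissue factor pathway inhibitor, differed by 0.56 ± 0.13 and TMOD3, which caps actin filaments, by 0.56 ± 0.13. The forkhead factor FOXN2 differed by 0.65 ± 0.15, the zinc finger gene ZMAT2 by 0.70 ± 0.13 and the uroplakin gene UPK3B by 0.60 ± 0.12. NPIPB3 and NPIPB4 differed by 0.70 ± 0.13 and 0.66 ± 0.12. They belong to a family of near-identical copies and TAS2R31 has close paralogs, so these values may include signal from related genes.

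**Figure D2:**
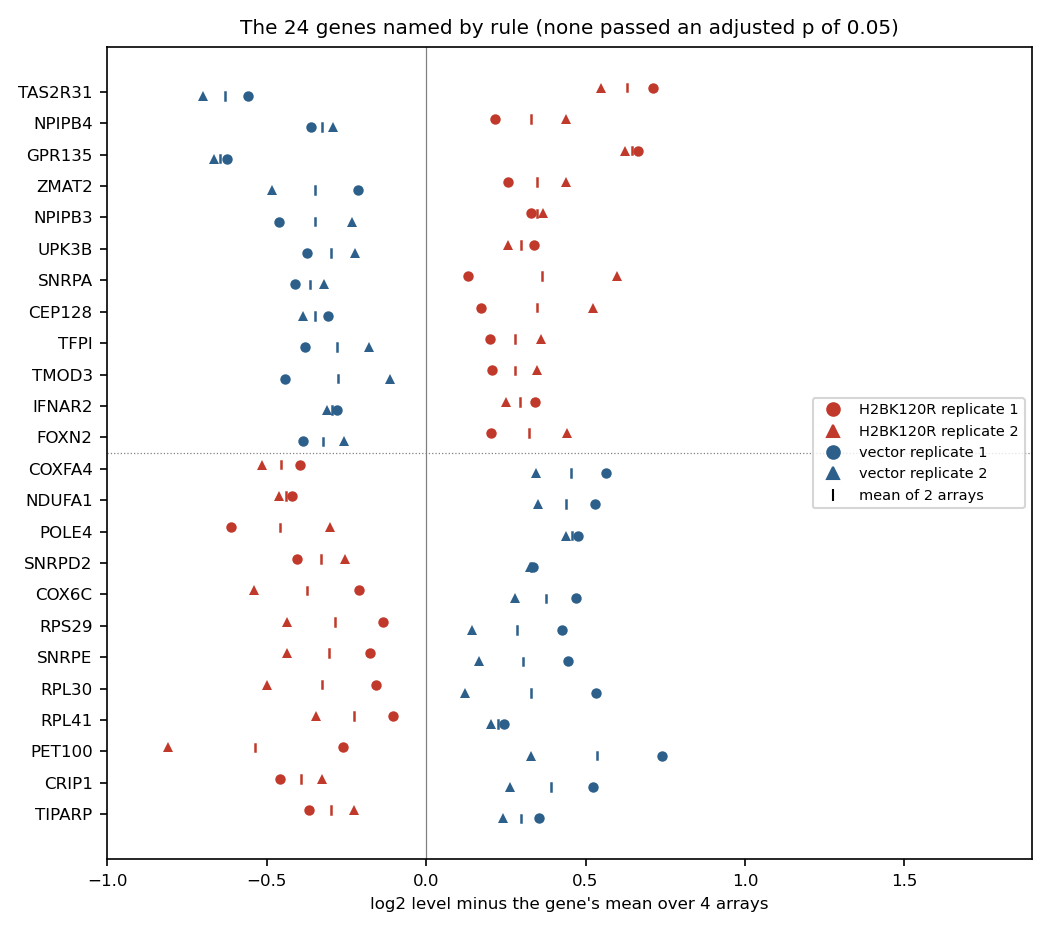
Log2 level minus the gene's mean over the 4 arrays (horizontal axis) for the 24 genes named by rule (rows, higher with H2BK120R above the dotted line and lower below it), with red for H2BK120R, blue for vector, circles for replicate 1, triangles for replicate 2 and ticks for group means. Both arrays of a group lie on the same side of both arrays of the other for every gene shown, as the rule required, and none of the 24 passed an adjusted p of 0.05.

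Over all 21448 probe sets, 0 passed a Benjamini-Hochberg adjusted p of 0.05 in limma, and the smallest adjusted p was 0.492. At an unadjusted p under 0.05 there were 1437 probe sets (6.70%), 777 higher and 660 lower with H2BK120R, where 1072 would be reached by chance. The count was 495 without H2BK120R replicate 2, 744 without H2BK120R replicate 1 and 2427 without vector replicate 2, and 1292 when the replicate 1 arrays were set against the replicate 2 arrays. Both arrays of one group lay above both of the other for 36.5% of probe sets, and chance alone gives 33.3%. The median standard error was 0.28, or 0.19 for probe sets brighter than the median and 0.31 for dimmer ones, and the median 95% confidence interval extended 0.62 to either side. In data simulated for this comparison over 21448 genes, the same test recovered 17.3% of 200 genes changed by 1 on the log2 scale and 89.9% of those changed by 2. With 2 arrays against 2, an exact permutation test of a single gene cannot give a two-sided p below 0.333.

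Gene groups showed small shifts. Of 44 gene lists fixed before the data were examined, 6 were shifted against the other genes by limma's camera test with its preset correlation of 0.01 (adjusted p under 0.05 over the lists), 4 lower and 2 higher with H2BK120R. None of the calls held when the correlation was estimated for each list. The estimates were -0.016, -0.021 and -0.023 for the ribosomal, oxidative phosphorylation and proteasome lists, below the preset. A larger correlation was therefore not why these calls were lost. With an estimated correlation, camera takes its p-values from the 2 residual degrees of freedom of the fit, and with the preset from far more. The unadjusted camera p of the ribosomal list thus went from 2.7e-11 to 0.0169. The estimates were 0.30 for replication histones other than H2B, 0.16 for mitosis and 0.05 for DNA repair. In data simulated without correlation between genes, the estimated setting missed a ribosomal shift of 0.2 in every run. That setting could hardly call a shift of this size here. Its adjusted p-values, given with each list below, therefore do not tell whether the list was shifted.

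The genes of the cytosolic ribosome gave the clearest shift. Of 52 listed ribosomal protein genes 31 were measured, and 30 of them were lower with H2BK120R, with a median difference of -0.22, or 14.1% lower (camera adjusted p = 1.19e-09). With an estimated correlation the adjusted p was 0.481. Both arrays with the mutant lay below both vector arrays for 20 of the 31 genes, and 12 had an unadjusted p under 0.05. RPL30, with a limma adjusted p of 0.045, was the 1 member that passed when adjusted over the list alone. RPS29 and RPL41, named above, did not belong to the fixed list. RPLP1 (-0.44 ± 0.13), RPS12 (-0.32 ± 0.11) and RPL11 (-0.33 ± 0.12) did not pass. Averaged over the list, the arrays with H2BK120R deviated from each gene's mean by -0.10 each and the vector arrays by 0.10 and 0.11.

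Oxidative phosphorylation genes, which encode the respiratory complexes and ATP synthase, were lower for 38 of the 48 measured members, with a median difference of -0.20 (camera adjusted p = 8.91e-07). The adjusted p was 0.481 with an estimated correlation. Adjusted over the list alone, 4 members fell, which were COXFA4, NDUFA1, COX6C and COX7C, a further cytochrome c oxidase subunit whose difference was -0.67 ± 0.19. Over all probe sets 0 passed. Proteasome subunits showed a shift of similar size, with 21 of 28 measured genes lower, 6 higher and a median of -0.19 (camera adjusted p = 1.51e-04, and 0.575 with an estimated correlation). PSMC3, an ATPase of the regulatory particle, had the smallest p of these at -0.61 ± 0.16, and PSMA1, PSMD4 and PSMD6 differed by -0.51 ± 0.18, -0.34 ± 0.14 and -0.44 ± 0.18. None of the proteasome genes passed when adjusted over the list alone.

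Replication-dependent histone genes other than H2B were lower for 33 of 36 measured members, with a median difference of -0.15 (camera adjusted p = 1.06e-04, and 0.780 with an estimated correlation). H4C11 differed by -0.35 ± 0.13, H4C14 by -0.27 ± 0.12, H2AC4 by -0.29 ± 0.13 and H4C1 by -0.58 ± 0.26, and 0 members passed over the list alone. The arrays with the mutant differed from each other here, with a mean deviation of 0.01 in replicate 1 and -0.16 in replicate 2. Without H2BK120R replicate 2 the median was -0.05 and the call was lost (adjusted p = 0.337). Among 10000 random lists matched on genomic length, a share of 0.0786 had a median as low as that of the histone list.

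Genes acting in mitosis and in homologous recombination were shifted the other way. All 49 genes of the list for the G2/M phase and mitosis were measured, and 40 were higher with H2BK120R, with a median of 0.15 (camera adjusted p = 3.09e-04, and 0.780 with an estimated correlation). The members with the smallest p were CCNA2, which encodes cyclin A2 (0.74 ± 0.25), and the cytokinesis factor ECT2 (0.32 ± 0.11). The proliferation marker MKI67 (0.28 ± 0.12) and the condensin subunit NCAPH (0.27 ± 0.13) followed, and 0 members passed over the list alone. CCNA2 was at 13.52 in both arrays with H2BK120R, but at 13.29 in vector replicate 1 and 12.28 in vector replicate 2. The list for homologous recombination and the Fanconi anaemia pathway had 26 of 30 measured genes higher, 2 lower and a median of 0.21 (camera adjusted p = 0.00217, and 0.780 with an estimated correlation). XRCC2, PALB2, MRE11 and ATM differed by 0.46 ± 0.17, 0.31 ± 0.14, 0.38 ± 0.17 and 0.37 ± 0.17, and 0 members passed over the list alone. Both calls were lost without H2BK120R replicate 2, where the medians were 0.10 (adjusted p = 0.181) and 0.16 (adjusted p = 0.155). The mitosis call was also lost without vector replicate 1, the array that correlated least with the others, where the median was 0.04 (adjusted p = 0.122).

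**Figure D3:**
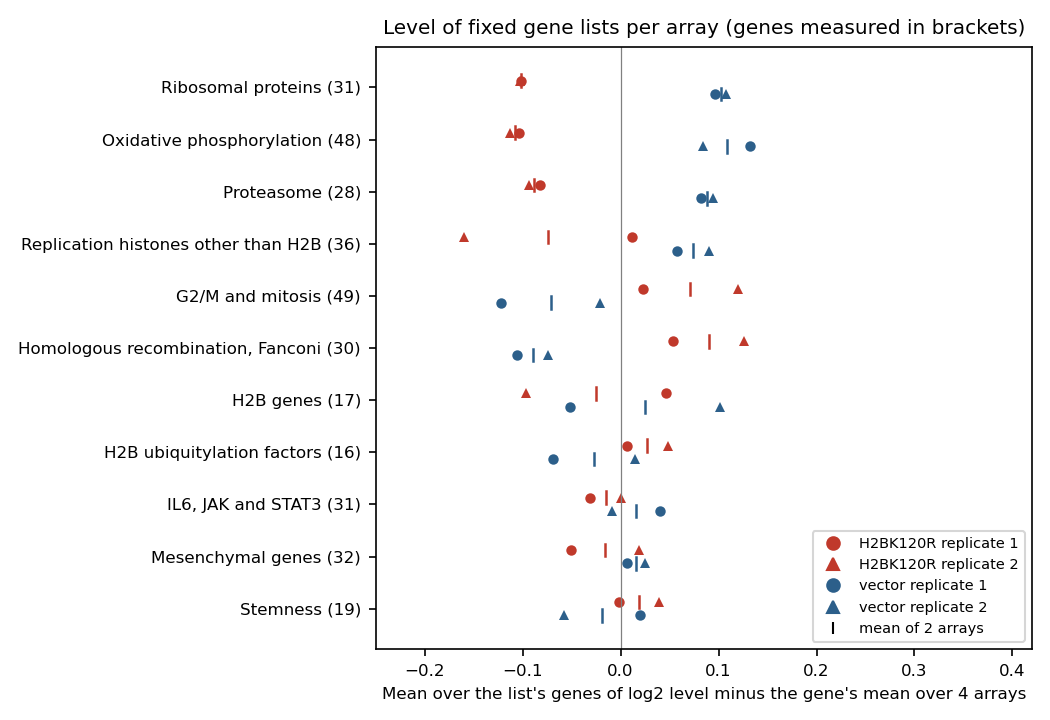
Mean over the genes of each list of the log2 level minus the gene's mean over the 4 arrays (horizontal axis), for 11 of the fixed lists (rows, with the number of measured genes), with red for H2BK120R, blue for vector, circles for replicate 1, triangles for replicate 2 and ticks for group means. The arrays of the 2 groups are well apart for ribosomal proteins, oxidative phosphorylation and the proteasome, while H2BK120R replicate 1 lies at 0.01 and replicate 2 at -0.16 for the other replication histones.

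The other 38 lists were not shifted at this threshold, and the smallest adjusted p among them was 0.117. They included the factors that write and erase the mark under study. The 16 measured genes for H2B ubiquitylation had a median difference of 0.07 (adjusted p = 0.630), with 10 higher and 6 lower. The 4 with the smallest p were the E2 enzyme UBE2A (-0.25 ± 0.13), the E3 ligase subunit RNF40 (-0.29 ± 0.15), BARD1 (0.34 ± 0.23) and RTF1 (0.22 ± 0.15), and none passed. The 11 measured H2B deubiquitylase genes had a median of 0.08 (adjusted p = 0.564). Among 16 measured genes for H3K4 and H3K79 methylation, which H2Bub1 is known to promote, 10 were higher and 6 lower, with a median of 0.18 (adjusted p = 0.117). KMT2A, a histone H3K4 methyltransferase, rose by 0.65 ± 0.16 when adjusted over the list alone (limma adjusted p = 0.025) and had an adjusted p of 0.604 over all probe sets. KMT2C and KMT2D, of the same enzyme family, differed by 0.45 ± 0.18 and 0.42 ± 0.17, and CXXC1, also on the list, by -0.68 ± 0.24. None of these 3 passed.

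Signalling and identity lists were likewise within the spread of the other genes. The median was -0.03 for the IL6, JAK and STAT3 list (adjusted p = 0.985), -0.06 for NF-kB and inflammation (0.690), -0.08 for the interferon response (0.687), -0.04 for mesenchymal genes (0.687), 0.09 for epithelial genes (0.564) and 0.05 for stemness (0.687). The epithelial cadherin gene CDH1 differed by 0.60 ± 0.15 and had an adjusted p of 0.070 over its list alone and 0.650 over all probe sets. In the list for S phase the median was 0.05 (adjusted p = 0.630), for MYC targets -0.06 (0.473) and for p53 targets 0.03 (0.985). Lists of cell type markers were not shifted either. The camera adjusted p was 0.117 for leukocytes, whose median was 0.21, and 0.630 for fibroblasts. It was 0.576 for alveolar type II cells, endothelium, airway epithelium, gut and liver, and neurons. For the amino acid response, NOTCH target and hypoxia lists the median was below 0 and the mean above it, and their adjusted p-values were 0.687, 0.985 and 0.985. Leukocyte markers passed after quantile normalization (adjusted p = 0.0436) and without the variance trend (0.0432), and MYC targets without vector replicate 1 (0.0248). The p-values above the threshold do not show that these genes were equal in the 2 groups.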

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

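The count of probe sets at an unadjusted p under 0.05 and its values under each setting were chosen only after the result was seen. Under every setting, arrays left out included, 0 probe sets passed an adjusted p of 0.05 in limma, and the same held at 1.5-fold or 2-fold. The count at an unadjusted p under 0.05 was 1437 as reported, 903 with the dimmest 50% of probe sets left out, where fewer were tested, and between 495 (without H2BK120R replicate 2) and 2427 (without vector replicate 2) with 1 array left out. It was 744 without H2BK120R replicate 1. In these fits the lone array of a group is assumed to vary like the other group. Of the 44 gene lists 6 were shifted as reported, and 0 with an estimated correlation. With fry, which asks whether a list's genes move one way on balance and does not compare them with other genes, 0 passed and the smallest adjusted p was 0.0558. The self-test missed a list shift of 0.2 with an estimated correlation in every run, so that loss does not by itself exclude a shift of this size. With 1 array left out, between 3 (without H2BK120R replicate 2) and 7 lists passed, and apart from the fewer probe sets or arrays the cause of these changes was not tested. The ribosomal, oxidative phosphorylation and proteasome lists stayed past the threshold in each of these fits. All 6 lists also passed with each other normalization and filter, without the variance trend and on ranks. Robust estimation did not enter the list test, so that setting repeated the main one. Further lists passed in some settings, for 8 in all with quantile normalization (TGF-beta targets and leukocyte markers added), 9 without the dimmest 50% (TGF-beta targets, immediate early genes and senescence secretion), 7 without the trend (leukocyte markers) and 7 each without vector replicate 1 (MYC and TGF-beta targets) and vector replicate 2 (NRF2 targets), at adjusted p-values from 0.0222 to 0.0436. Over all settings, gene lists kept their side of the threshold in 615 cases, lost it in 16 and gained it in 9. The 615 include the robust setting. None of the named genes passed in any of 490 cases. No called direction reversed, but for lists a reversal was not checked with the estimated correlation, ranks or fry. The LDOC1 difference ranged from 0.19 to 0.52 and the H2B median from -0.14 to 0.03 with 1 array left out. In the paired fit with the replicate block, 0 probe sets passed, 1846 had an unadjusted p under 0.05 and 6 lists were shifted. Arrays sharing a number deviated together with a correlation of 0.14 across probe sets, and 2 pairs are too few to show that the numbers pair them. The planned change of pseudocount was not run, because the values were already log2. Dim probe sets had the wider errors.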

Other observations

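The gene families below, the test of other small-subunit families, the other splits of the arrays and the setting of medians with 1 array left out against 2 standard errors were chosen only after the results were seen, while leaving out each array was planned. Among 17 gene families picked by symbol, 6 were shifted by limma's camera test with the preset correlation. With an estimated correlation 0 were, and the smallest camera adjusted p was 0.406. The estimated setting rests on 2 residual degrees of freedom and left little room to call a family. Centromere and centrosome genes (CENP and CEP symbols), of which 5 also belong to the mitosis list, were higher with H2BK120R for 42 of 54 members, with a median of 0.15 (adjusted p = 0.00274). CEP128, CEP19 and CEP290 differed by 0.70 ± 0.16, 0.84 ± 0.30 and 0.41 ± 0.16 (SE) and did not pass over all probe sets. CEP128 was already among the named genes. The median of this family was 0.11 without H2BK120R replicate 2 and 0.13 without vector replicate 1, and the call was lost in both fits. Bitter taste receptor genes were higher for 16 of 21 members, with a median of 0.20 (camera adjusted p = 0.00618). Without vector replicate 1 their median was 0.17 and the call was lost. TAS2R31, TAS2R19 and TAS2R4 differed by 1.26 ± 0.23, 1.22 ± 0.33 and 1.04 ± 0.30. The family was examined because TAS2R31 was among the named genes, and its members are similar in sequence and mostly dim, with a mean level of 4.29.

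Genes with SNRP and LSM symbols encode Sm, LSm and other small nuclear ribonucleoprotein components, and none belongs to a fixed list. Of 21 members 15 were lower, with a median of -0.15 (camera adjusted p = 0.0325). SNRPD2, SNRPE and SNRPA were already among the named genes, so this family is not independent of them. The median was -0.21 (adjusted p = 0.254) without H2BK120R replicate 1 and -0.20 (adjusted p = 0.257) without vector replicate 2, and the member SNRPA, a U1 snRNP protein outside the Sm ring, differed by 0.73. Chaperonin subunit genes were lower for 8 of 9 (median -0.20, adjusted p = 0.0325). Their median was -0.15 (adjusted p = 0.210) without H2BK120R replicate 1 and -0.15 (adjusted p = 0.263) without vector replicate 2. Collagens (31 of 41 lower, median -0.18) and olfactory receptors (216 of 348 lower, median -0.11) each had an adjusted p of 0.0325, which became 0.0634 and 0.253 after quantile normalization. Without H2BK120R replicate 2 the adjusted p was 0.196 for collagens and 0.383 for olfactory receptors, and without vector replicate 1 it was 0.180 and 0.608. The olfactory receptor median was then -0.02 and -0.01, while the collagen median was -0.19 and -0.16. The 448 zinc finger genes with ZNF symbols had a median of 0.06 (adjusted p = 0.476).

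The lower ribosomal, respiratory and proteasome genes share high levels and compact genes, so brightness or gene length might account for them. Random lists matched on mean level reached a median as low in a share of at most 1e-04 for each of the 3 lists, the smallest that 10000 lists can give, and random lists matched on genomic length in a share of at most 0.0041. The medians of the 3 lists stayed below 0 with each array left out. The median closest to 0 was -0.15, more than 2 standard errors over the members from 0. Such errors take genes as replicates and do not measure the spread between arrays. Other families of small subunits did not settle whether such genes move in general. Mitochondrial ribosomal proteins had a median of -0.10 ± 0.03 (SE over members), genes with SNRP and LSM symbols -0.15 ± 0.07 and mitochondrial translocases -0.04 ± 0.05. Without vector replicate 2 these medians were -0.06, -0.20 and 0.07. Differences in RNA quality, transcript length, cell density or growth between the cultures were not tested and stay open beside an effect of the mutant histone.

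The same matching was made for the other 3 lists that passed. For the replication histones other than H2B the share with a median as low was 1e-04 by mean level and 0.0786 by genomic length, where the random lists had a median of -0.06, so this list did not stand apart from genes of similar length. The share with a median as high was 0.0012 and 9e-04 for the mitosis list, and 4e-04 and 9e-04 for the DNA repair list.

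The higher mitosis genes may reflect vector replicate 1, in which they were lowest: without that array the list's median was 0.04 ± 0.04 (SE over members). The DNA repair genes were different, with a median of 0.16 ± 0.04 without it, so that array alone does not account for them, although leaving out H2BK120R replicate 2 ended both calls. Errors over members do not measure the spread between arrays. An effect of the mutant histone and a difference in growth between the cultures both stay open for these lists.

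A copy number difference between the lines could move neighbouring genes together. Over 849 windows of 40 neighbouring genes brighter than the median, in the gene order of the RefSeq table, the largest distance of a window's median from that of all genes was 0.17, between DMTF1 and BRI3, against 0.17 and 0.11 for the other splits of the arrays. A permutation test with 1000 shuffles of the gene order gave p = 0.118, which leaves smaller or shorter differences open.

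The 4 arrays can be split into pairs in 3 ways, too few for a share under 0.05. The real split gave 1437 probe sets at an unadjusted p under 0.05 and the highest other split gave 1292. It gave 6 shifted gene lists, and the highest other split gave 2. That split, H2BK120R replicate 1 and vector replicate 2 against the rest, shifted the replication histones other than H2B (median 0.08) and the H2B genes (median 0.16), each with an adjusted p of 0.0107, and the H2B median was larger than the -0.09 of the real split. The remaining split, H2BK120R replicate 1 and vector replicate 1 against the rest, shifted the mitosis list (median -0.12, adjusted p = 0.0439). The mitosis and histone lists were thus also shifted between pairs that mix both cell lines. The ribosomal, oxidative phosphorylation, proteasome and DNA repair lists passed in neither of the other splits. For both counts 1 of the 3 splits, the real one, gave a count as large. The split of replicate 1 arrays against replicate 2 arrays called 1 probe set at an adjusted p of 0.05, and the real split called 0.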
